A study of Mus musculus with 66 samples.

How the data were processed

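The series measured polyadenylated RNA in progenitors of the ventral spinal cord made from mouse embryonic stem (ES) cells. Per the labels, the cells were fixed in glyoxal, stained for intracellular markers and sorted, with 10000 to 15000 cells per population, before RNA extraction and sequencing. The labels give each library a genotype (WT or MUT), a day (D5, D7, D9 or D11), a progenitor domain (p1, p2 or pM), an NFIA gate (NFIAn or NFIAp) and a replicate number. These labels placed all 66 libraries in 26 groups, of which 1 group held 1 library, 10 held 2 and 15 held 3. The labels do not name the mutated gene. They do not state whether libraries that share a day and a replicate number came from separate cultures, so p-values measure only the spread between these libraries.

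Per the submitters' processing notes, the authors mapped reads to mm10 and normalised the counts with DESeq2. No version of either is given in the sources used here. The deposited signal is a normalised read count, that is, a read count divided by the DESeq2 size factor of its library. It was checked on the table: the value of 1 read was estimated in each library by least squares from its smallest values upward, and division by it gave whole numbers within 0.01 for 100% of values. These recovered reads ranged from 8.738 to 30.83 M per library with a median of 24.33 M. The table holds 24410 gene symbols and no mitochondrially encoded gene. Among 55 pairs of replicates none were identical, and the lowest chi-squared per degree of freedom between replicates was 25.49, so the spread between replicates exceeded counting error. No library was left out.

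Each comparison used limma with a variance trend on log2(normalised count + 1), with a mean for every group fitted over all 66 libraries, so that small groups share an estimate of spread. The group with 1 library was assumed to vary like the others. Genes with a value of at least 10 in at least 2 libraries were tested, which left 15714 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene past an adjusted p of 0.05 was counted as called. Differences over several domains are means of the differences within each domain. An F test in limma asked whether the change over time differed among the domains. Values are given as log2 difference ± SE of the fit with the libraries per side.

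Gene lists written from textbook knowledge of the neural tube were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists of a comparison. Camera with an estimated correlation and fry were run beside it, and each list's members were also adjusted over the list alone. The choice of comparisons, tests, filter, pseudocount, gene lists, rule for naming genes and the first set of alternatives was made before the data were examined. Named genes are first the 5 rising and 5 falling genes of largest log2 difference per comparison among called genes. These needed a mean of at least 50 in the higher group and libraries that did not overlap between the groups within any domain compared, so every library shows the direction of a gene named by rank. This need not hold for the other named genes. Gene models, clones and pseudogenes were passed over. To these the rule adds up to 4 members of each list that passed camera, and fixed regulators of domain identity, time and glial fate. For the F test and the difference of differences between genotypes, the rule takes the 5 genes of smallest adjusted p in each direction. Some genes that these rules name are not reported here. Positions and gene types are from GENCODE M21 on GRCm38, in which 23375 symbols (95.8%) were found.

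The first set of alternatives was a pseudocount of 8, no filter, TMM scaling, edgeR and DESeq2 on the recovered reads, and a fit on only the compared groups. It also held the replicate number as a block, a correlation between libraries of the same genotype, day and replicate number, and leaving out each library in turn. The replicate number within each day as a block together with that correlation, and a repeat without 18 libraries of high deposited total, were chosen after seeing the data. Counts of called genes were also taken for other splits of the libraries into groups of the same sizes, 100 per comparison where that many exist. The fits were tested on simulated data of the same design with 100 genes changed at each of the sizes 2-fold and 4-fold. Without effects shared between libraries, 16% of 2-fold and 70% of 4-fold changes were recovered for time in p1, 65% and 94% for D5 to D7, 36% and 92% for the gate, and 54% and 93% for genotype at D11, with 4.55% to 7.25% of calls false. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.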

Results

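RNA from sorted ventral spinal cord progenitors was sequenced on 4 days of an ES cell differentiation, in 37 WT and 29 MUT libraries. Cells received bFGF at 10 ng/ml, the GSK3 inhibitor CHIR99021 at 5 µM from day 2, and retinoic acid at 100 nM with the Smoothened agonist SAG at 10 nM from day 3. Retinoic acid was withdrawn at day 5. The p1 gate, called p0-p1 in the series description, and the p2 gate hold progenitors of ventral interneurons, and pM holds progenitors of motor neurons. NFIAn and NFIAp cells are those below and above a gate on NFIA, a transcription factor of the onset of glial development. All MUT libraries are NFIAn, all WT libraries at D11 are NFIAp, and WT at D9 was sorted both ways in p2 and pM. Recovered reads per library were 8.738 M in MUT D5 p2 replicate 2 and between 20.29 and 30.83 M elsewhere, with 13491 to 15244 genes detected.

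The sum of normalised counts set 18 libraries apart, namely all of D7 replicate 3, D9 replicate 2 and D9 replicate 3. Their sums were 26.59 to 40.23 M against 17.85 to 25.5 M in the other 48. Ribosomal protein genes took 12.4% ± 3.31 (SD, n = 18) of their normalised counts against 7.27% ± 1.98 (SD, n = 48). Both genotypes and all domains sampled on these days are among the 18, which carry much of the D7 and D9 groups.

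**Figure D1:**
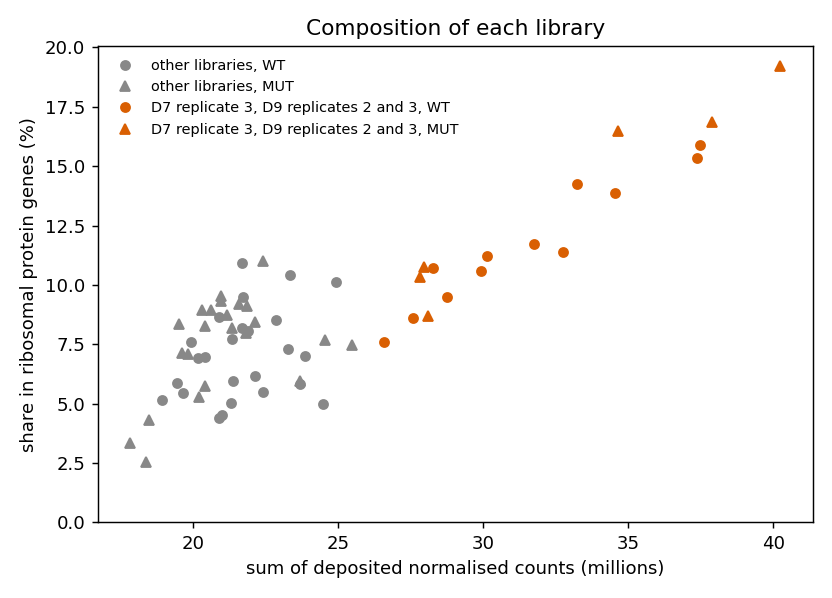
Sum of normalised counts per library (x axis, M) against the share taken by ribosomal protein genes (y axis, percent), with a point per library, circles for WT and triangles for MUT. The 18 libraries of D7 replicate 3 and D9 replicates 2 and 3 lie from 26.59 to 40.23 M, right of the other 48.

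The first question, set by the series title, is which genes change with time in every domain, and it was asked in WT as D11 minus D5 within each domain. Nfib and Nfia, transcription factors of the gliogenic switch, rose in all 3 domains. Nfib went from 1.45 ± 0.892 (SD, n = 3) to 2200 ± 636 normalised counts (SD, n = 2) in p2, and its log2 change was 9.15 ± 0.67 in p1, 9.84 ± 0.67 in p2 and 10.12 ± 0.73 in pM. On GRCm38 the protein coding genes Nfib (82290173 to 82705750), Nfia (97772734 to 98118874) and Lin28a (134003330 to 134018841) all lie on chromosome 4. Nfia rose by 6.8 ± 0.66, 6.48 ± 0.66 and 6.39 ± 0.72 in the same order. Lin28a, an RNA-binding protein that blocks maturation of let-7 microRNAs, changed by -8.63 ± 0.6, -6.87 ± 0.6 and -7.97 ± 0.65, from 4300 ± 901 (SD, n = 3) to 9.74 ± 1.58 normalised counts (SD, n = 2) in p1. All of these had limma adjusted p of 2.2e-09 or less with 2 libraries at D11 and 3 (p1, p2) or 2 (pM) at D5.

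Genes of early embryonic timing fell as a group. Of the 19 tested members, 14 fell in each domain, including Lin28b, Hmga2 and the nuclear receptor Nr6a1, and adjusted over the list alone the counts were 14, 15 and 14. The limma camera adjusted p with an estimated correlation was 0.0094 in p1, 0.0076 in p2 and 0.0054 in pM. Astroglial genes rose: 23, 23 and 21 of 33 were higher at D11 (23, 24 and 24 adjusted over the list alone), with adjusted p = 9e-05, 2e-05 and 8.8e-05 with an estimated correlation. Among them were the glutamate transporter Slc1a3 (log2 change 4.3, 4.99 and 5.27) and the lipid-binding protein Fabp7 of radial glia (8.66, 8.81 and 8.3). Late progenitor transcription factors rose in 15, 11 and 10 of 18 members (16, 12 and 10 adjusted over the list alone), with adjusted p = 0.0087, 0.051 and 0.073 with an estimated correlation. Oligodendrocyte lineage genes were higher in 9, 9 and 10 of 19 (9, 10 and 14 adjusted over the list alone), among them Cnp and Sox10, with adjusted p = 0.053, 0.044 and 0.0021 with an estimated correlation. In p1, however, mean Pdgfra went from 67.6 at D5 to 3.97 normalised counts at D11. Olig2 (17 to 25.8) and Olig1 (6.34 to 9.81) stayed low there, so the calls in p1 do not show a rise of the whole lineage program. Yet mean Sox10 at D11 was highest in p1, at 789 normalised counts against 208 in p2 and 470 in pM. Sox10 by itself therefore does not mark this lineage in p1, and the source of its RNA there was not tested.

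S phase genes fell in 23, 21 and 23 of 26 members (25, 23 and 26 adjusted over the list alone), such as the replication licensing factor Cdt1 (log2 change -2.74 ± 0.24 in p1, -2.26 ± 0.24 in p2, -2.41 ± 0.26 in pM). Their adjusted p was 0.00035, 0.0013 and 0.00018 with an estimated correlation. G2 and M phase genes fell in 25, 16 and 25 of 29 (28, 17 and 28 adjusted over the list alone), with adjusted p = 0.027, 0.19 and 0.025 with an estimated correlation. Genes of postmitotic neurons were higher at D11 in 22, 24 and 14 of 26 (22, 24 and 15 adjusted over the list alone), with adjusted p = 0.00035, 0.00074 and 0.025 with an estimated correlation. In pM the tubulin gene Tubb3 of neurons was among those that did not pass, at 0.68 ± 0.41 (adjusted p = 0.27). Mesenchyme markers moved with time too: 9 of 13 were higher in p2 at D11 (9 adjusted over the list alone), among them Postn and Dcn, with adjusted p = 0.32 with an estimated correlation. Lists of neurons and of other cell types were included as checks of what the gates hold. The share of differentiated cells in a gate was not measured. A change in that share cannot be told apart here from a change within progenitors, for these lists and the cell cycle lists.

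In limma, 4360 genes were called in p1 (2206 higher, 2154 lower), 4051 in p2 (2239 and 1812) and 3205 in pM (1683 and 1522). Of these, 2016 were called in all 3 domains in one direction, 1075 higher and 941 lower, where independent lists would share 33.7 and 24.1. Among the 6058 genes called in at least 1 domain, 89.2% had one fitted sign in all 3 and 28 were called in opposite directions in different domains. Day goes with the gate here, since D5 cells are NFIAn and D11 cells NFIAp. Single libraries weighed on the counts: p2 gave 2495 without WT D11 p2 replicate 2 and 2612 without replicate 3, pM gave 1834 without WT D11 pM replicate 2, 1976 without WT D5 pM replicate 2 and 2087 without WT D5 pM replicate 3, and the shared count was 1325 without WT D11 pM replicate 2.

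**Figure D2:**
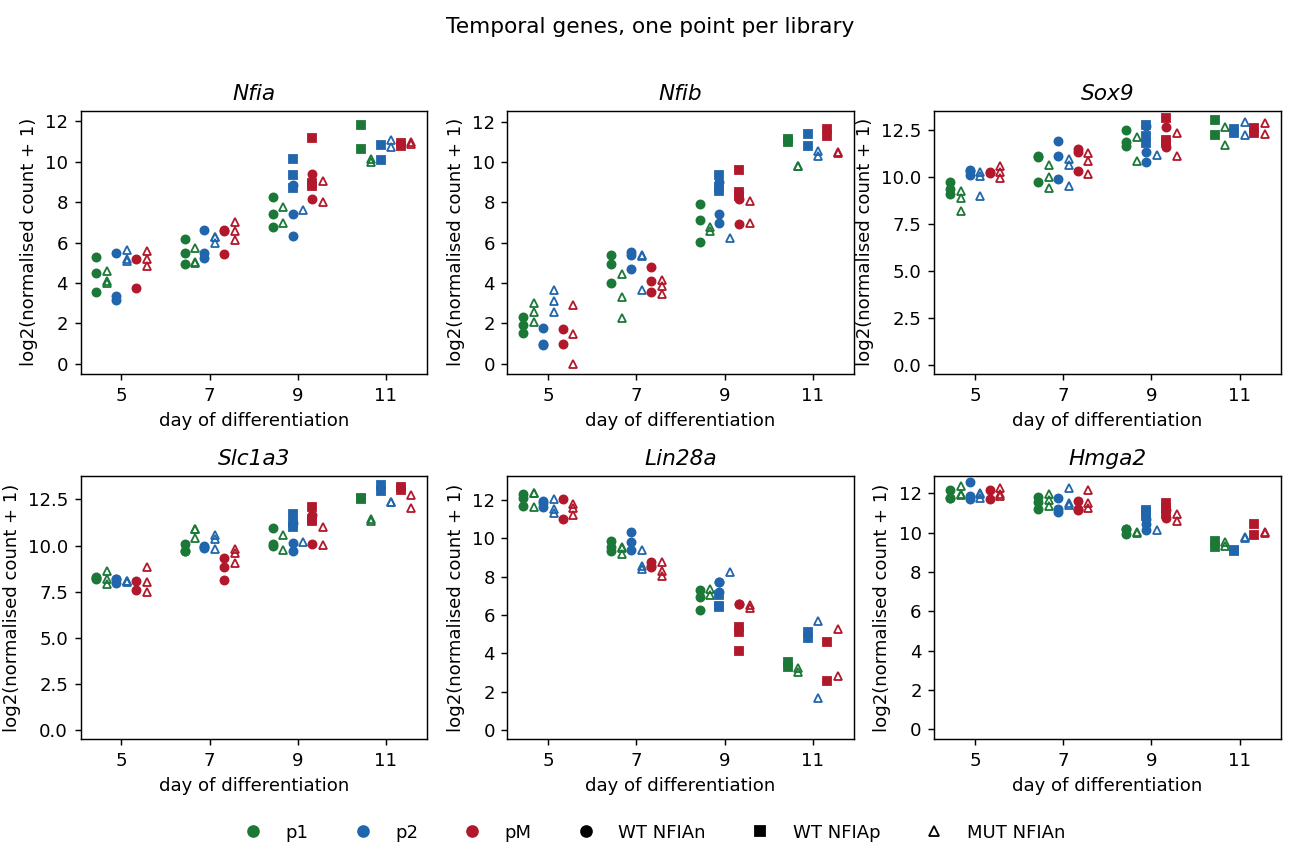
Log2 of the normalised count plus 1 (y axis) of 6 genes by day (x axis), with a point per library coloured by domain, filled circles for WT NFIAn, squares for WT NFIAp and open triangles for MUT. Nfib in WT goes from 0.88 to 3.91 normalised counts at D5 to between 1750 and 3140 at D11.

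Whether the change from D5 to D11 differed among the domains was asked with the F test. Neurod4, a proneural transcription factor, changed by 4.86 in p1, 0.76 in p2 and 0.08 in pM on the log2 scale (limma F test, adjusted p = 1.8e-07). The neuronal RNA-binding protein Elavl4 changed by 3.6, 1.91 and -0.84 (adjusted p = 4.1e-08). Ccnd1, the G1 cyclin D1, changed by 1.49, -0.02 and -3.65 (adjusted p = 1.9e-08), and its call in p1 itself ended without WT D11 p1 replicate 3. Serpine2, a protease inhibitor, rose most in pM with 0.85, 2.23 and 3.87 (adjusted p = 1.1e-06). The F test called 140 genes, all of them also called over time in at least 1 domain. Without WT D11 pM replicate 2 it called 88, with libraries of one genotype, day and replicate number treated as correlated 463, and without the 18 libraries of high total 252.

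The course of these changes was followed in WT steps of 2 days, with the same gate label on both days. The passage from NFIAn to NFIAp therefore falls in no step. In p2 and pM at D9 the NFIAn cells are only part of the domain, since NFIAp cells were sorted apart. From D5 to D7, neuronal genes rose and genes of the caudal embryo fell. Mean Tubb3 in p1 went from 767 to 7950 normalised counts, and a larger share of neurons in the gates was not tested as the source. Dcx, a microtubule protein of young neurons, rose by 3.78 ± 0.26 (SE, 9 libraries at D7 and 8 at D5). Cdx2, a transcription factor of caudal identity, changed by -4.23 ± 0.39 and the adaptor Grb7 by -5.77 ± 0.56. Postmitotic neuron genes rose in 19 of 26 members (21 adjusted over the list alone; adjusted p = 0.00013 with an estimated correlation) and neurogenic progenitor genes in 13 of 22 (14 adjusted over the list alone; 0.019). Neuromesodermal and mesodermal genes fell in 6 of 14 (9 adjusted over the list alone; adjusted p = 0.0053 with an estimated correlation). Motor neuron genes rose in 8 of 15 (10 adjusted over the list alone), with Lhx3 at 3.2 ± 0.3 and Isl1 at 2.4 ± 0.29, and adjusted p = 0.092 with an estimated correlation. Limma called 3073 genes, 1578 higher and 1495 lower. The count was 1333 with libraries of one genotype, day and replicate number treated as correlated, and the D7 groups hold 3 of the libraries of high total per genotype.

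From D7 to D9, 4 genes of the integrated stress response fell: Chac1, which degrades glutathione, changed by -4.41 ± 0.26, the kinase-like regulator Trib3 by -5.24 ± 0.56, asparagine synthetase Asns by -2.44 ± 0.15 and the transcription factor Atf4 by -1.42 ± 0.12 (SE, 8 libraries at D9 and 9 at D7). The list they belong to, which mixes heat shock with stress response genes, fell in 6 of 16 members and rose in 1 (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0068 with an estimated correlation). Neurogenic progenitor genes rose in 14 of 22 (14 adjusted over the list alone; 0.0068), with Hes6, which promotes neuronal differentiation, at 1.59 ± 0.16. S phase genes fell in 18 of 26 (20 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation) and G2 and M phase genes in 20 of 29 (23 adjusted over the list alone; 0.045). Nfib rose by 2.74 ± 0.36 and Nfia by 2.08 ± 0.35, and Lin28b changed by -1.98 ± 0.23. The step leaves out NFIAp cells of D9, whose neurogenic progenitor genes were lower and G2 and M phase genes higher than in NFIAn cells. Mean Neurog2 in p2 was 1610 normalised counts at D7, 1940 in NFIAn and 999 in NFIAp cells at D9. In pM it was 4210, 6760 and 5070. The rise of the former list and the fall of the latter may thus come in part from the gate. Both days hold libraries of high total. Limma called 2261 genes, 990 higher and 1271 lower, and the count was 872 with libraries of one genotype, day and replicate number treated as correlated and 1333 with only the compared groups. Without the libraries of high total 801 were higher and 797 lower, so the balance of directions is not settled.

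From D9 to D11, compared among NFIAp cells of p2 and pM, astroglial genes rose in 18 of 33 members (21 adjusted over the list alone; limma camera adjusted p = 3.4e-05 with an estimated correlation). Aldoc, the aldolase of astrocytes, rose by 3.13 ± 0.29, the proteoglycan Bcan by 5.83 ± 0.94 and the Wnt inhibitor Apcdd1 by 5.32 ± 0.79 (SE, 4 libraries at D11 and 6 at D9). Ddc, the aromatic amino acid decarboxylase, changed by -4.07 ± 0.21, from 2460 to 119 normalised counts. G2 and M phase genes fell in 24 of 29 (29 adjusted over the list alone; adjusted p = 0.0029 with an estimated correlation) and S phase genes in 17 of 26 (23 adjusted over the list alone; 0.0029). Cholesterol synthesis genes fell in 11 of 20 (16 adjusted over the list alone; adjusted p = 0.0044 with an estimated correlation), with the isomerase Idi1 at -0.83 ± 0.17. Mesenchyme markers rose in 5 of 13 (8 adjusted over the list alone) in the same libraries, with adjusted p = 0.28 with an estimated correlation. Limma called 1593 genes, 968 higher and 625 lower. The count was 842 with libraries of one genotype, day and replicate number treated as correlated, 714 without the libraries of high total (325 higher and 389 lower), which include most of the D9 side, 962 without WT D11 p2 replicate 3 and 985 without WT D11 pM replicate 3.

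Genes that differ between neighbouring domains were sought over all 4 days in WT. Higher in p2 than in p1 were Vsx1 (5.38 ± 0.48) and Foxn4 (5.33 ± 0.6), transcription factors of p2 and its interneurons, Nkx6-1 (4.06 ± 0.32), which p2 shares with pM, and the Notch ligand Dll4 (3.56 ± 0.47). Lower in p2 were the transcription factors Dbx1 (-3.38 ± 0.35) and Dbx2 (-2.6 ± 0.22) of p0 and p1, the Wnt antagonist Frzb (-3.2 ± 0.43) and Prdm13 (-3.1 ± 0.61). All values are log2 differences with SE and 11 libraries on each side. Vsx1 lies on chromosome 2 (150680702 to 150689360) and Dbx1 on chromosome 7 (49631499 to 49636849). Of the p0 and p1 identity genes 6 of 9 were lower in p2 (7 adjusted over the list alone; limma camera adjusted p = 6.4e-07 with an estimated correlation), and of the p2 identity genes 5 of 9 were higher (6 adjusted over the list alone; 0.0031). Dorsal progenitor genes such as Zic1 and Msx3 were lower in p2 in 6 of 13 (8 adjusted over the list alone; adjusted p = 0.00038 with an estimated correlation). Motor neuron genes were higher in p2 in 7 of 15 (9 adjusted over the list alone; 0.0031), led by Nkx6-1 and Lhx3, which act in p2-derived neurons as well. Neural crest markers were lower in p2 in 3 of 13 (6 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Nfia differed by -0.23 ± 0.31 (adjusted p = 0.86) and Lin28b by -0.23 ± 0.21 (adjusted p = 0.74). Limma called 288 genes, 201 higher and 87 lower in p2. The count was 1043 with libraries of one genotype, day and replicate number treated as correlated, 436 with DESeq2, 182 with only the compared groups and 126 without the libraries of high total.

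Higher in pM than in p2 were the motor neuron progenitor factors Olig1 (5.19 ± 0.5) and Olig2 (4.59 ± 0.53) and the motor neuron factors Isl1 (4.17 ± 0.27) and Mnx1 (3.2 ± 0.5). Lower in pM were Vsx1 (-5.07 ± 0.51), Gata2 (-3.3 ± 0.61), a transcription factor of p2-derived neurons, the GTPase Rab30 (-3.38 ± 0.18), Pax6 (-1.39 ± 0.12) and Irx3 (-1.9 ± 0.31), with 9 libraries in pM and 11 in p2. Olig2 lies on chromosome 16 (91225457 to 91228677). Motor neuron progenitor genes were higher in 6 of 8 members (6 adjusted over the list alone; limma camera adjusted p = 4.4e-08 with an estimated correlation), and p2 identity genes lower in 6 of 9 (7 adjusted over the list alone; 0.0018). Motor neuron genes were higher in 6 of 15 (8 adjusted over the list alone; 0.0018). S phase genes were lower in pM in 4 of 26, and in 12 adjusted over the list alone (adjusted p = 0.0053 with an estimated correlation). Limma called 386 genes, 108 higher and 278 lower in pM. The count was 971 with libraries of one genotype, day and replicate number treated as correlated, 222 without the libraries of high total and 233 without WT D11 pM replicate 2.

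Sorting WT cells on NFIA at D9 asks what distinguishes cells that have reached the NFIAp state on the same day. In NFIAp cells the hyaluronan synthase Has2 was higher by 3.06 ± 0.5 (limma adjusted p = 0.00095), the homeodomain protein Hopx by 1.94 ± 0.41 (0.027) and the mitotic kinase Cdk1 by 1.12 ± 0.2 (0.0031), with 6 NFIAp and 5 NFIAn libraries of p2 and pM. The proneural factor Neurog1 was lower by -1.34 ± 0.3 (0.036) and the growth arrest gene Gadd45g by -0.94 ± 0.19 (0.017). Nfia RNA averaged 904 normalised counts in NFIAp and 355 in NFIAn cells, a log2 difference of 1.37 ± 0.44 that did not pass (adjusted p = 0.23). Oligodendrocyte lineage genes were higher in 1 of 19 members and in 9 adjusted over the list alone (limma camera adjusted p = 0.0038 with an estimated correlation), and astroglial genes in 0 of 33 and in 5 adjusted over the list alone (0.0086). G2 and M phase genes were higher in 4 of 29, and in 20 adjusted over the list alone (adjusted p = 0.0083 with an estimated correlation). Neurogenic progenitor genes were lower in 3 of 22, and in 7 adjusted over the list alone (adjusted p = 0.029 with an estimated correlation). Neural crest markers were higher in the same NFIAp libraries in 1 of 13, with Prrx1 at 3.52 ± 0.74 (1.49 and not called with a pseudocount of 8), and in 5 adjusted over the list alone (adjusted p = 0.027 with an estimated correlation), and mesenchyme markers in 0 of 13 and in 5 adjusted over the list alone (adjusted p = 0.084 with an estimated correlation).

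Limma called 32 genes between the gates, 23 higher and 9 lower in NFIAp, and 1355 genes had an unadjusted p under 0.05. Without the libraries of high total 2 libraries per gate are left, and 8 genes were called, 2 of them among the 32. Hopx was then at 1.61 ± 0.61, Cdk1 at 1.49 ± 0.31, Neurog1 at -1.38 ± 0.48 and Gadd45g at -1.05 ± 0.32, near their values over all libraries but not called. The count also moved with the model: it was 454 with libraries of one genotype, day and replicate number treated as correlated, 130 with DESeq2, 13 with edgeR and 1 with only the compared groups. In the correlated fit, 33 of the 79 genes named for the gate gained a call and 0 lost one. On simulated data with such shared effects, that fit recovered 70% of 2-fold gate changes against 50%. A gene that did not pass above may therefore differ between the gates. Leaving out libraries one at a time gave 73 without p2 NFIAn replicate 1 or pM NFIAn replicate 1, 14 and 8 without p2 NFIAn replicates 2 and 3, 6 and 17 without p2 NFIAp replicates 1 and 3, 7 without pM NFIAn replicate 3 and 12 without pM NFIAp replicate 1.

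MUT and WT were compared on each day as the mean of the differences within the 3 domains. The same few genes differed strongly from D5 on. Counts of calls fell on each day when libraries of one genotype, day and replicate number were treated as correlated, and rose on each day when an effect of the day and number was taken as shared by both genotypes. Grb10, an imprinted adaptor of growth factor receptors (chromosome 11, 11930508 to 12038683 on GRCm38, protein coding), was lower in MUT by -3.03 ± 0.21 at D5, -3.7 ± 0.2 at D7, -4.73 ± 0.25 at D9 and -4.87 ± 0.25 at D11, with limma adjusted p of 9.8e-15 or less. Its mean fell within MUT from 258 ± 93.5 normalised counts at D5 (SD, n = 9) to 47.4 ± 14.6 at D11 (SD, n = 6), against 2040 ± 487 (SD, n = 8) and 1390 ± 388 (SD, n = 6) in WT. The splicing factor Hnrnph1, also on chromosome 11, was lower by -1.21, -1.82, -2.02 and -2.02, and its D5 call ended with libraries of one genotype, day and replicate number treated as correlated. Xlr3a, of a multi-copy family on the X chromosome whose reads may be shared between copies, was higher by 2.09, 2.96, 2.19 and 1.81. The Y-linked translation factor Eif2s3y was higher by 1.47, 2.06, 1.71 and 1.47. In all, 10 genes were called in one direction on all 4 days, the others being Cnp, Cdk5rap3, Mfap2, Hnrnph3, Xlr3b and Pla2g1b. Genes called at both D5 and D11 numbered 23 in one direction and 0 in opposite directions, where independent lists would share 1.54.

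**Figure D3:**
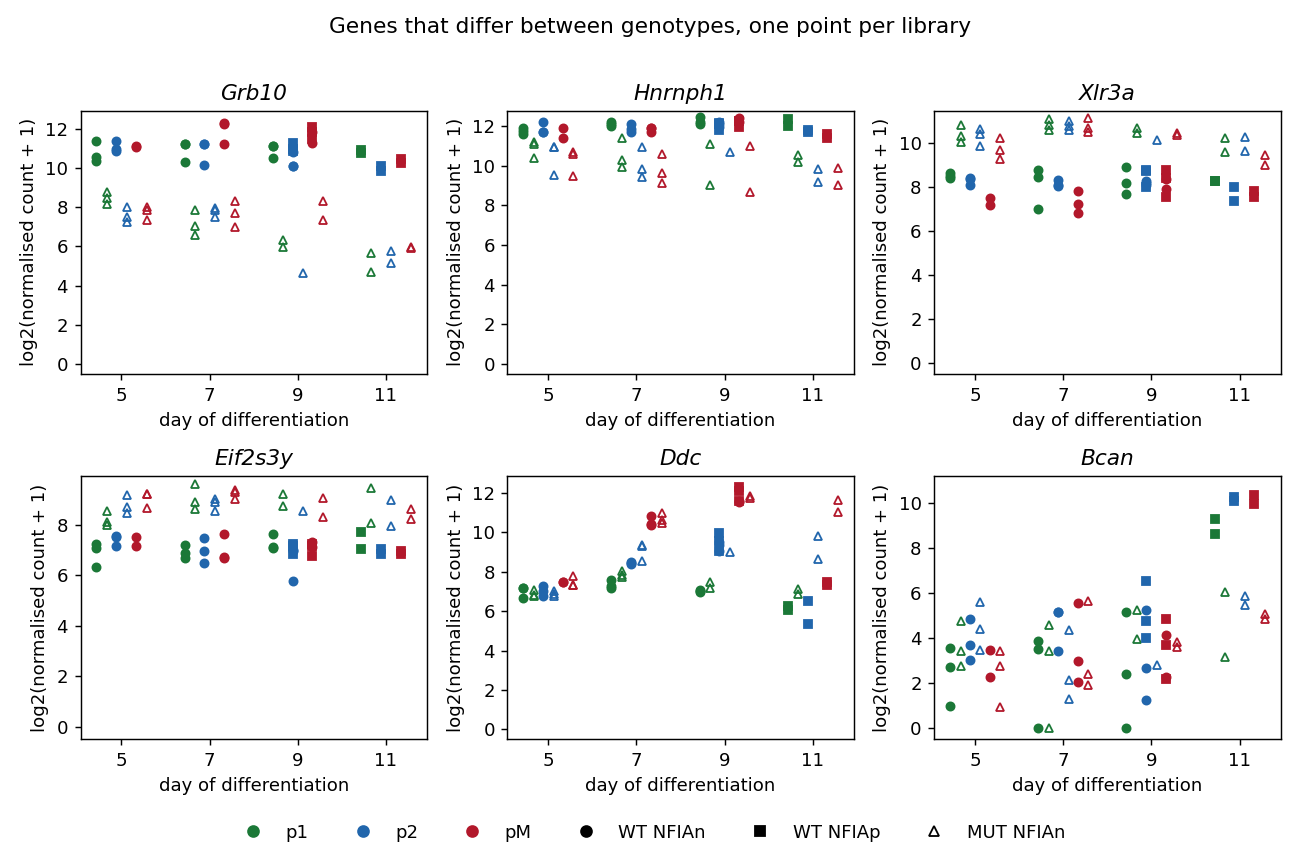
Log2 of the normalised count plus 1 (y axis) of 6 genes by day (x axis), with a point per library, open triangles for MUT and filled symbols for WT. Grb10 lies below in MUT on every day, with means of 258 against 2040 normalised counts at D5, while Bcan separates at D11, with 38.8 against 938.

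At D5, the comparison of 9 MUT with 8 WT libraries also found the Y-linked helicase Ddx3y higher in MUT by 3.02 ± 0.5 (limma adjusted p = 0.00037) and the neuropeptide Npy lower by -2.04 ± 0.26 (3e-06). Nfia differed by 0.62 ± 0.35 (adjusted p = 0.76) and Lin28a by -0.01 ± 0.32 (adjusted p = 1). Limma called 72 genes, 27 higher and 45 lower in MUT, and no gene list passed camera with an estimated correlation. The count was 11 with libraries of one genotype, day and replicate number treated as correlated, 138 with DESeq2, 394 with only the compared groups and 144 without the libraries of high total. It was higher than 72 with the replicate number within each day as a block beside that correlation. It fell to 39 without MUT p1 replicate 2 or MUT p2 replicate 2, 47 without MUT p2 replicate 3 or MUT pM replicate 3, 38 without MUT pM replicate 1 and 37 without MUT pM replicate 2. Among WT libraries it was 41 without p1 replicate 3 or p2 replicate 3, 42 without p2 replicate 1, 43 without pM replicate 2 and 33 without pM replicate 3.

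At D7, with 9 libraries per genotype, the imprinted cell cycle inhibitor Cdkn1c was lower in MUT by -1.81 ± 0.3 (limma adjusted p = 0.00021) and Ddx3y higher by 2.87 ± 0.48 (0.00019). Posterior Hox genes were lower in 4 of 15 members and in 7 adjusted over the list alone, with Hoxa9 at -2.68 ± 0.58 (0.0056), and adjusted p = 0.17 with an estimated correlation. The call of Hoxa9 at D7 ended with edgeR, with only the compared groups and with the correlated fit. Limma called 319 genes, 122 higher and 197 lower. The count was 37 with libraries of one genotype, day and replicate number treated as correlated, 193 without the libraries of high total (110 higher and 83 lower), 493 with DESeq2, 104 with only the compared groups and 210 without MUT p2 replicate 3. It was higher than 319 with the replicate number within each day as a block beside that correlation.

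At D9, with 5 MUT and 8 WT NFIAn libraries and MUT p2 held by 1 library, Hoxa9 was lower in MUT by -4.05 ± 0.73 (limma adjusted p = 0.0013), and the hypoxia-responsive genes Bnip3 and Slc2a1 were higher by 1.08 ± 0.22 (0.0046) and 0.84 ± 0.18 (0.011). Hypoxia and glycolysis genes were higher in 2 of 20 members and in 8 adjusted over the list alone (adjusted p = 0.063 with an estimated correlation), and posterior Hox genes lower in 2 of 15 and in 4 adjusted over the list alone (adjusted p = 0.095 with an estimated correlation). Without the libraries of high total 2 libraries per genotype are left, in 2 domains, and none of these 3 genes was called, with Hoxa9 at -2.13 ± 1.29, Bnip3 at 1.13 ± 0.39 and Slc2a1 at 1.02 ± 0.31. Limma called 110 genes, 56 higher and 54 lower. The count was 17 without the libraries of high total, 28 with libraries of one genotype, day and replicate number treated as correlated, 222 with DESeq2, 168 with no filter and 17 with only the compared groups. It was 36 without MUT p2 replicate 3, which removes that domain, 68 without MUT p1 replicate 3 and 69 without MUT pM replicate 3.

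Set against WT NFIAp cells of p2 and pM at D9, 3 MUT libraries had lower oligodendrocyte lineage genes in 3 of 19 members and in 6 adjusted over the list alone (limma camera adjusted p = 0.0085 with an estimated correlation), with S100a1 at -3.39 ± 0.59 and Cnp at -1.14 ± 0.23 against 6 WT libraries. Cnp, on chromosome 11, was also lower in MUT than in WT NFIAn cells, by -0.99 at D5, -0.98 at D7 and -0.99 at D9, so its difference is not particular to this comparison. The aldo-keto reductase Akr1c13 was lower by -4.12 ± 0.63 (adjusted p = 0.00014) and Otor by -4.28 ± 0.7 (0.00047), the latter not called with edgeR. Limma called 119 genes, 45 higher and 74 lower, and the gate differs with the genotype here. Without the libraries of high total 1 library per genotype is left, in 1 domain, so the 21 calls there say little; S100a1 was then at -2.75 ± 0.86, Cnp at -0.94 ± 0.49 and Otor at -2.03 ± 1.32, none of them called. The count was 49 with libraries of one genotype, day and replicate number treated as correlated, 261 with DESeq2, 179 with no filter and 45 with only the compared groups. It was 26 without MUT p2 replicate 3, 55 without MUT pM replicate 3 and 76 without WT p2 NFIAp replicate 3 or WT pM NFIAp replicate 1.

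At D11, with 6 libraries per genotype, genes of astrocytes were lower in MUT NFIAn than in WT NFIAp cells. Aldoc was lower by -2.38 ± 0.26 (limma adjusted p = 9.9e-09), the folate enzyme Aldh1l1 by -4.65 ± 0.73 (3.1e-05) and Bcan by -4.69 ± 0.84 (3e-04), with 938 ± 359 normalised counts of Bcan in WT and 38.8 ± 20.7 in MUT (SD, n = 6 each). Thrsp, a regulator of lipid synthesis, was lower by -7.4 ± 0.7 (2.5e-10). Ddc was higher by 2.67 ± 0.19 (1.5e-14). Of the astroglial genes 12 of 33 were lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 0.0043 with an estimated correlation). S phase genes were higher in MUT in 11 of 26 (16 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation) and cholesterol synthesis genes in 6 of 20 (14 adjusted over the list alone; 0.0068), led by the reductase Dhcr7 at 1.21 ± 0.21. Early embryonic timing genes were higher in 4 of 19 and in 8 adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). Nfia differed by -0.21 ± 0.42 (adjusted p = 0.84), Nfib by -0.97 ± 0.42 (0.2) and Sox9, a factor of glial specification, by -0.06 ± 0.34 (0.96).

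Limma called 650 genes at D11, 283 higher and 367 lower in MUT, and genotype goes with the NFIA gate on this day. Nfia RNA was at 1650 ± 476 normalised counts in the MUT NFIAn libraries and 1970 ± 867 in the WT NFIAp libraries (SD, n = 6 each), while WT NFIAp cells at D9 averaged 904, so the gate labels do not part these libraries by Nfia RNA. The count was 107 with libraries of one genotype, day and replicate number treated as correlated, 152 with only the compared groups and 1529 without the libraries of high total, none of which are from D11. It was 381 without MUT p1 replicate 3, 410 without WT p2 replicate 2 and 339 without WT pM replicate 2. On all 4 days, calls of single genes between MUT and WT are less certain than their adjusted p shows if libraries of a day and number share an effect that is separate in each genotype, and not if both genotypes share it, in which case the fit called more genes on each of these days and over time.

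**Figure D4:**
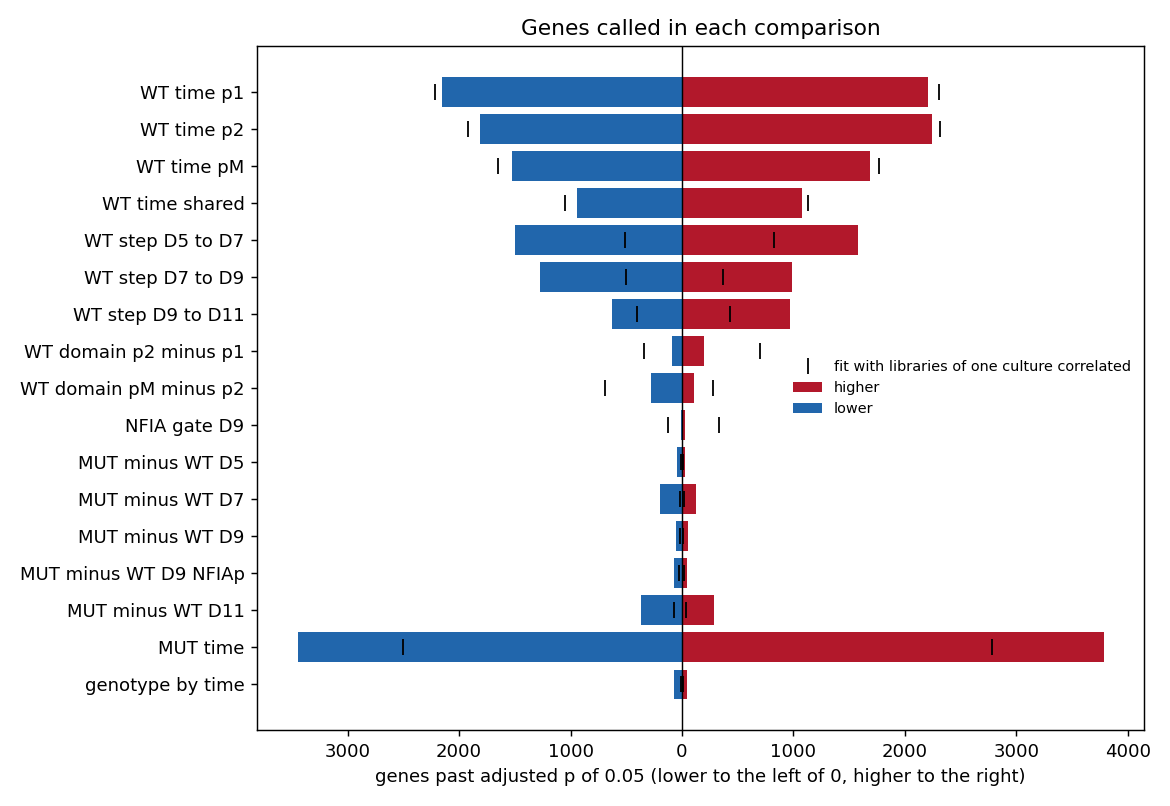
Genes past an adjusted p of 0.05 in each comparison (x axis, counts), lower to the left of 0 in blue and higher to the right in red, with ticks for the fit in which libraries of one genotype, day and replicate number are correlated. The D11 genotype comparison has 650 genes by the bars and 107 by the ticks, whereas time in p1 has 4360 and 4514.

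The change over time in MUT shared its main features with WT. Nfia rose by 5.72 ± 0.38 and Nfib by 7.85 ± 0.39, and Lin28a changed by -8.18 ± 0.34 (SE, 6 libraries at D11 and 9 at D5, mean over domains). Late progenitor transcription factors rose in 17 of 18 members (17 adjusted over the list alone; limma camera adjusted p = 0.029 with an estimated correlation). Astroglial genes rose in 21 of 33 and fell in 4 (the same counts adjusted over the list alone; 0.0029). Early embryonic timing genes fell in 15 of 19 and rose in 1 (the same counts adjusted over the list alone; 0.016). Limma called 7233 genes, 3783 higher and 3450 lower. Of these, 5284 (73.1%) stayed called with libraries of one genotype, day and replicate number treated as correlated. The count averages over domains with more libraries per side, so it cannot be set against the WT counts within single domains.

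Whether time acted differently in the genotypes was tested as a difference of differences. Aldoc rose less in MUT by -1.76 ± 0.34 (limma adjusted p = 0.003), and astroglial genes differed downward in 7 of 33 and upward in 1 (14 and 2 adjusted over the list alone; adjusted p = 7e-04 with an estimated correlation). S phase genes differed upward in 4 of 26 and in 15 adjusted over the list alone (adjusted p = 0.0028 with an estimated correlation), led by the replication factor Cdc6 at 1.23 ± 0.25. Cholesterol synthesis genes differed upward in 2 of 20 and in 4 adjusted over the list alone (0.014). Ddc changed by 2.11 in MUT and -0.65 in WT, a difference of 2.76 ± 0.25 (1.7e-10). Nfia differed by -0.84 ± 0.55 (adjusted p = 0.74) and Nfib by -1.86 ± 0.56 (0.13). Limma called 121 genes, 46 upward and 75 downward, and by gate label WT passes from NFIAn to NFIAp over this span while MUT does not, although Nfia RNA rose in both. The count was 14 with libraries of one genotype, day and replicate number treated as correlated, a fit in which the calls of Aldoc and Cdc6 ended, and 182 without the libraries of high total. It was higher than 121 with the replicate number within each day as a block beside that correlation. It was 76 without WT D11 p2 replicate 2, 71 without WT D11 pM replicate 2 and 79 without WT D5 pM replicate 3.

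By chromosome, a summary chosen after the values were seen, the median MUT minus WT difference over tested genes was lower on chromosomes 8 and 11 than on the other autosomes and X. On chromosome 8 it was -0.23 at D5, -0.24 at D7, -0.22 at D9 and -0.2 at D11, and on chromosome 11 it was -0.22, -0.22, -0.22 and -0.2. On the other autosomes and X medians ran from -0.13 to 0.13, and on chromosome 6 from -0.13 to -0.03. The Y chromosome was left out of this summary, and its gene Eif2s3y was higher in MUT by 1.47 to 2.06. The 2012 tested genes on these chromosomes were called on at least 1 day in 11.2% of cases against 5.5% elsewhere. A value per library was the chromosome median relative to the midpoint of the MUT and WT means of its day and domain. The same median over the other autosomes was subtracted. Each of the 29 MUT libraries lay below all 37 WT libraries, with the highest MUT value at -0.012 and the lowest WT value at 0.019 on chromosome 8. On chromosome 11 they were -0.041 and 0.033. This centring sets the genotypes apart around 0 wherever they differ. The chromosomes were also picked on these libraries, so the separation is no independent test. Of the 319 genes called at D7, 115 lie on these chromosomes and 112 of those were lower in MUT.

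**Figure D5:**
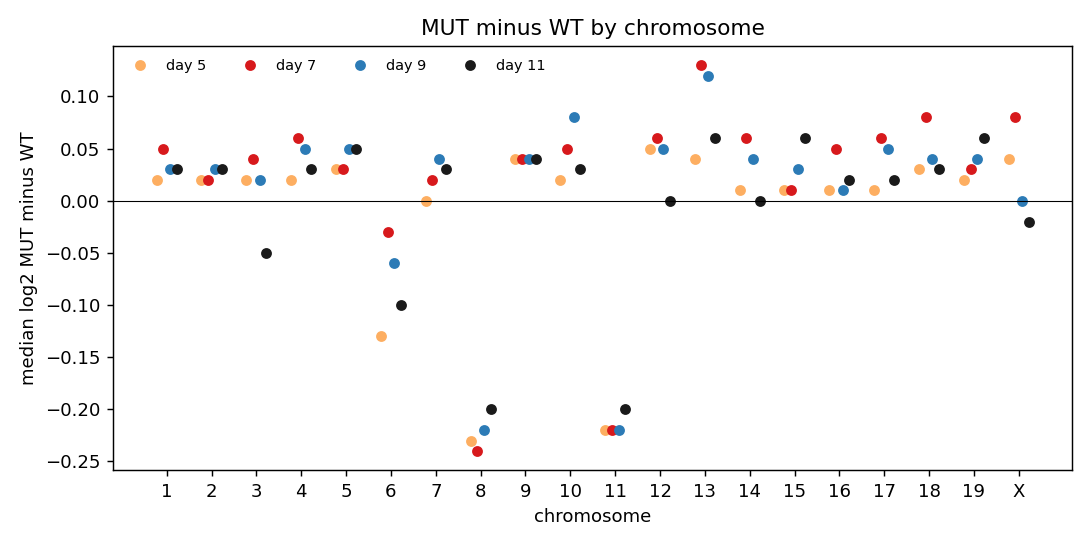
Median log2 difference MUT minus WT over tested genes (y axis) for each autosome and X (x axis), with a point per day. Chromosomes 8 and 11 lie between -0.24 and -0.2 on all 4 days, and the others between -0.13 and 0.13.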

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

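The tests of transcript length and of sequencing depth and the repeat without the libraries of high total were chosen only after the result was seen.

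A tested difference between domains singled out 140 genes whose change from D5 to D11 in WT was not the same in p1, p2 and pM. For the methyltransferase gene Prmt8 the change in pM minus that in p1 was -4.69 on the log2 scale. For Ccnd1 it was -5.14, for Elavl4 -4.43, for Neurod4 -4.78 and for the stress gene Gadd45g -3.33. It was 6.02 for the serotonin receptor gene Htr6, 5.19 for Papln and 5.69 for Trhr, which are listed at 0 in p1 on both days, so their sizes depend on the pseudocount. For Serpine2 it was 3.02. For Ccdc184 the change in p2 minus that in p1 was 7.62.

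A tested difference between genotypes in the change over time singled out 121 genes. Higher in MUT minus WT were Ddc by 2.76, Npy by 2.62, Cdkn1a by 1 and Slco4a1 by 2.94. Lower were Thrsp by -6.95, Slc15a2 by -4.45, C1qtnf5 by -3.73, Trhr by -2.76 and Tagln2 by -1.78. With libraries of one genotype, day and replicate number treated as correlated, 14 genes were called in place of the 121. More than 121 were called with the replicate number within each day as a block beside that correlation.

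The 18 libraries of high total differ from other libraries of their groups. Within the 6 groups at D7, the log2 difference of replicate 3 from replicates 1 and 2 fell with transcript length across 10727 genes, with a median Spearman rho of -0.526 over groups and a range of -0.58 to -0.421; genes are not independent replicates. The median difference was 1.16 in the 10% of genes with the shortest transcripts, -0.59 in the 10% with the longest and 2.01 in ribosomal protein genes. Sequencing depth is argued against, with a ratio of median reads of 1.03, and so is GC content, with a median absolute rho of 0.07. For D7 replicate 3, a loss or gain of RNA by transcript length in library preparation is a candidate cause; length and GC content were not set against the D9 libraries. It stays a hypothesis, since the labels give no preparation batch and a biological difference between the cultures was not tested.

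At D7, 4 of 100 splits of the libraries called as many genes as the 319 between MUT and WT, and the highest other split called 4776. That split put all 6 libraries of replicate 3 on one side, and a count several times the real one points to a structure of the samples. From D7 to D9, 2 of 100 splits called as many as the real 2261, with 2650 in the highest other, and between p2 and p1 2 of 100 called as many as 288, with 420 in the highest other. These splits also follow the libraries of high total in part: 5 of 6 such libraries lay on one side in the domain split, and 2 of 8 on the D9 side in the other. Under 5% of the splits drawn, the real one included, reached these counts. Only 100 of 4000 possible splits were drawn at D7 and from D7 to D9, and 100 of 24000 between p2 and p1. Libraries that share a day and number are also not exchangeable, as the split with 4776 calls shows. These splits therefore exclude neither chance in the grouping nor a batch that follows the replicate number. Without the libraries of high total the counts were 193 at D7, 1598 from D7 to D9 and 126 between p2 and p1.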

How the results depend on the processing

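The repeat without the 18 libraries of high total and the replicate block within each day combined with a culture correlation were chosen only after the result was seen. Replicate numbers do not formally pair libraries: the correlation of residuals between libraries of one genotype, day and number had a median of 0.17 over 74 pairs but went down to 0.009. Between libraries of one day and number but different genotype the median was 0.16 over 89 pairs, so the number ties libraries across genotypes about as strongly as within one. Between libraries of different number in one genotype and day the median was -0.1 over 134 pairs, and 61 of 65 libraries correlated best with one of their own number. If libraries of one genotype, day and number share an effect, the limma adjusted p of comparisons between days over several domains is too small, and that between genotypes is too small where the effect is separate in each genotype. On simulated data with such effects, separate in each genotype and named culture effects here, 38.4% of calls were false from D5 to D7, 42.2% between genotypes at D5 and 47.4% at D11, against 4.55%, 7.41% and 6.77% with a correlation for them, the culture correlation. For time within p1, with 1 such library per set, they were 13.5% and 10.9%. With effects shared by both genotypes on a day, the first shares were 1.16% at D5 and 2.44% at D11, and 7.11% and 7.5% with the replicate block within each day, which recovered 86% and 87% of 2-fold changes against 74% and 68%. The correlation within a genotype, day and number was 0.375, and 0.0939 beside the replicate block within each day. All simulated effects were given the 0.375. For genotypes the false shares under separate effects thus come from a stronger separate effect than the 0.0939 left beside the block. For comparisons between genotypes these values, pooled over days, favour effects shared by both genotypes on a day over separate ones. A smaller separate part stays open, and single days were not assessed.

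With the culture correlation, genes called numbered 463 by the F test between domains, 1333 from D5 to D7, 872 from D7 to D9, 842 from D9 to D11, 1043 between p2 and p1, 971 between pM and p2 and 454 between the NFIA gates. Between genotypes they numbered 11 at D5, 37 at D7, 28 at D9, 49 at D9 against NFIAp, 107 at D11 and 14 in the difference over time. The share of the main calls that stayed called was 43.4% from D5 to D7, 38.6% from D7 to D9, 15.3% between genotypes at D5, 11.6% at D7, 24.5% at D9 and 16.5% at D11, and 100% for domains and gate.

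With the replicate block, the step from D9 to D11 called 2621 genes, the gate 64 and genotypes at D5 111. With the replicate block within each day and a culture correlation, time in p2 called 6362, time in pM 5205, all 3 domains 3592, the F test 468, D5 to D7 4916, D7 to D9 4503, D9 to D11 3868, p2 against p1 1579, pM against p2 1086 and the gate 674. For time within a domain and the steps, this block takes the spread between replicate sets of a day out of the error. Those higher counts are therefore no remedy for shared effects, and the block was not simulated for a comparison between days. Between genotypes this block gave 492 at D5, 1630 at D7, 453 at D9, 404 at D9 against NFIAp, 2468 at D11 and 609 over time.

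Without the libraries of high total, the F test called 252, D9 to D11 714, p2 against p1 126, pM against p2 222 and the gate 8. Between genotypes this gave 144 at D5, 193 at D7, 17 at D9, 21 at D9 against NFIAp, 1529 at D11 and 182 over time. These libraries kept apart, 12.7% of the D9 genotype calls stayed called, with 2 libraries per side left, and Dlx2 at D9 turned from 2.99 to -0.69. The cause was not tested.

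With only the compared groups, the F test called 82, D7 to D9 1333, p2 against p1 182, the gate 1, and genotypes 394 at D5, 104 at D7, 17 at D9, 45 at D9 against NFIAp and 152 at D11. DESeq2 called 436 between p2 and p1, 130 at the gate, 138 at D5, 493 at D7, 222 at D9 and 261 at D9 against NFIAp. EdgeR called 13 at the gate, a pseudocount of 8 gave 234 by the F test, and no filter gave 168 at D9 and 179 at D9 against NFIAp.

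Leaving out each library in turn gave 3191 to 3988 genes for time in p1, 2495 to 3517 in p2, 1834 to 2327 in pM, 1325 to 1904 in all 3 and 88 to 163 by the F test. The steps gave 2165 to 3331, 1576 to 2831 and 962 to 1785 in order of day. The domain comparisons gave 200 to 350 and 233 to 416, and the gate 6 to 73. Genotypes gave 33 to 88 at D5, 210 to 366 at D7, 36 to 116 at D9, 26 to 104 at D9 against NFIAp and 339 to 751 at D11. Time in MUT gave 6555 to 7042 and the difference over time 71 to 164. The balance of higher and lower calls turned under at least 1 alternative for time in p1 and pM, all 3 steps, genotypes at D7, D9, D9 against NFIAp and D11, and the difference over time. With the replicate block within each day, D7 to D9 gave 2396 higher and 2107 lower, and genotypes at D7 933 and 697. For the step from D7 to D9 this block leaves the spread between replicate sets of a day out of the error, so its counts are not a sound alternative there. With DESeq2, genotypes at D11 gave 431 and 396. Without MUT D9 p2 replicate 3, that domain leaves the D9 comparison.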

Other observations

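The repeat without the libraries of high total and the tests of imprinted loci, of the Grb10 region, of chromosomes 8 and 11, and of the steps from D7 to D9 and D9 to D11 were chosen only after the result was seen.

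Further groups of genes moved with time in WT. Posterior Hox genes rose in p1 in 7 of 15 members (8 adjusted over the list alone) and in p2 in 6 (6 adjusted over the list alone), with Hoxb6 at 2.73 ± 0.22 in both, and limma camera adjusted p = 0.037 and 0.05 with an estimated correlation. Genes of the p53 response fell in 10 of 15 members in p1 and 10 in p2 (11 and 10 adjusted over the list alone; adjusted p = 0.00074 and 0.0041 with an estimated correlation), among them Ccng1 at -1.72 ± 0.21 in p2. Neuromesodermal genes were lower at D11 in 10, 8 and 7 of 14 members in p1, p2 and pM (10, 9 and 8 adjusted over the list alone; adjusted p = 0.0094, 0.014 and 0.025 with an estimated correlation). Dorsal progenitor genes rose from D9 to D11 in 4 of 13 members (5 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Neural crest markers fell from D7 to D9 in 5 of 13 (5 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation).

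The D11 difference between genotypes goes with the NFIA gate, and 70.2% of the 650 called genes had a sign opposite to the D9 gate difference, against 58.5% of other genes. An earlier stage of MUT cells stays open: 45.7% had a sign opposite to the change from D5 to D7, against 45.2% of other genes, but a delay at D11 need not follow that first step, and 69.5% had a sign opposite to the change from D7 to D9, against 61.6%. For the step from D9 to D11 the share was 85.2%, against 56.7%, which is partly fixed by the WT D11 libraries that both differences use. The sign of the D5 difference was shared by 182 of the 283 genes higher in MUT and by 258 of the 367 lower ones. A share of 71.8%, against 61.1% of other genes, was also computed, which is above what these counts give over all 650. A difference between the lines that does not depend on the day may contribute, but the excess over other genes is uncertain. The mutation, the stage, the gate and the line cannot be parted at D11, since no MUT library is NFIAp and no WT library of that day is NFIAn.

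Chromosomes 8 and 11 had lower medians in MUT on every day. When each chromosome was divided by position into 3 parts, all 24 medians over parts and days were -0.11 or lower, as a difference in copy number of whole chromosomes would give. Length, GC content and abundance of the genes are argued against, since the adjusted median nearest 0 was -0.22, and so are the libraries of high total, since the median nearest 0 at D5 and D11, which hold none, was -0.2. Gains of these chromosomes recur in cultured mouse ES cells, so that a share of WT cells with an extra copy, or of MUT cells lacking one, is a candidate explanation; no DNA was analysed here. A stricter bound set earlier for chromosome 11, a median lower than -0.2 on every day, was missed at D11 with -0.196.

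Calls between MUT and WT were shared across days. Of the genes called at D7, 73.4% had one sign at D5 and D11, against 59.8% of genes not called. For these genes as a set, that leaves a difference between the lines that does not depend on the day open. Only 10 genes were called in one direction on all 4 days. The libraries of high total are argued against as the source, since D5 and D11, which hold none, shared 15 times the calls of independent lists. Imprinted genes were called on at least 1 day in 22% of cases (11 of 50), against 6.17% of other genes (Fisher's exact test, two-sided p = 2e-04), but this was prompted by Grb10 and Cdkn1c and counts neighbours as independent: with 1 gene per cluster and without the clusters of these genes, 2 of 18 were called (11.1%, Fisher's exact test, two-sided p = 0.31), so a difference in imprinting stays open. Of the other tested genes within 1 Mb of Grb10, 14.3% (1 of 7, Ddc) were called. Ddc differed by -0.08 at D5, 0.43 at D7 and 0.09 at D9. It was called only at D11, where it was higher in MUT by 2.67, opposite to Grb10. Ddc is thus no sign of a fall of the region on all days. A change of the region of Grb10 stays open.

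Other splits of the libraries tested how often another grouping gave as many calls. Libraries that share a day and number are not exchangeable, since 61 of 65 correlated best with their own number. Such splits break up these sets. They show where the real count stands among the splits drawn, and exclude neither chance nor effects carried by these sets. The real split alone, 1 of 100, reached 3073 from D5 to D7 (highest other 399), 1593 from D9 to D11 (977), 386 between pM and p2 (111), 32 at the gate (19), 72 at D5 (10), 110 at D9 (29), 7233 over time in MUT (4679) and 121 in the difference over time (66). At D9 against NFIAp it was 1 of 40, with 119 and 28. At D11, 2 of 100 splits reached 650, and the highest other, 683, set replicate 3 against replicate 2. The within-day replicate block there called 2468. Within a domain, the time comparisons have groups of 2, so no splits were counted.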
